A study of Mus musculus with 8 samples.

How the data were processed

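Total RNA of frozen gastrocnemius muscle was extracted with Trizol and made into paired-end libraries with a NEBNext Ultra kit, per the labels' protocols. The deposited values are whole-number counts per Ensembl gene, 49315 genes in each of 8 files, not normalized. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2, with the builds GRCm38 and mm10, are named in the submitters' processing notes without their roles. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here, so genes with near-identical copies or overlapping neighbours have uncertain counts. Gene symbols and coordinates come from GENCODE M21 on GRCm38, which matched 49056 of the 49315 identifiers, and 44858 had identical start and end. No entry was left out as naming no gene.

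Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the ages, which left 19571, and libraries were scaled by TMM. A quasi-likelihood model with robust spread estimates held the 4 ages over all 8 libraries, with 4 residual degrees of freedom, and gave 6 pairwise contrasts, a test across the ages and, in a separate model, a slope on age in months. Calls had a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of F. Fold changes of genes near 0 counts depend on the prior count. CPM are scaled by TMM, and means are given with the SD of 2 libraries. Totals of 42404254 to 59245029 counts per library set the precision.

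Lists of genes, 42 in all of which 41 had at least 5 tested members, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, with fry for direction and for mixed change. Named genes have a symbol that is no clone or predicted name, an average log2 CPM of at least 2, a call and no overlap of the groups. Up to 12 higher and 12 lower genes were named for 30 against 3 months, up to 5 each way for other pairs, and 5 for the ages and the slope. From each list described, up to 4 members with the lowest p were named, or 3 with the highest level for cell types and quality. Genes outside this rule are said to have been chosen after their values were seen. A gene that the rule would name is not reported here, and no other was named in its place.

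Alternatives were RLE size factors, library totals alone, no low count filter, a filter of 1 CPM in 2 libraries and an average log2 CPM of 1, DESeq2 1.42.0, limma-voom, only the 4 libraries compared, a replicate block, a minimum change of 1.5 times, a prior count of 0.5 for lists, and each library left out. Leaving out a library leaves 1 library at that age, assumed to vary like the other ages. Added after seeing the data were the library set as a term with 3 residual degrees of freedom, tests without the 3 month libraries, and counts without mitochondrial and repeat genes. The set of a library was taken from a summed level of 9 kidney genes above or below 1 CPM.

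The procedure was tested on simulated negative binomial counts made from the real means, spreads and library sizes. In 5 runs with 200 changed genes among 19571, at most 14 unchanged genes were called for 30 against 3 months, and a list of 30 genes raised 1.5-fold was called in 5. Genes were drawn independently of each other, so these runs cannot show how the preset correlation does where genes of a list vary together. In 10 runs with a set effect and no age effect, the fit with the set as a term called at most 10 genes for 30 against 3 months and the fit without it at most 1. The spreads of these runs came from the fit without the set, so they already held set differences. The 3 month libraries were taken to belong to the set with kidney transcripts. These runs therefore do not give the rate of false calls of the fit with the set on the real data. Shared controls were weighed against 20 simulated sets of unchanged groups.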

Results

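Gastrocnemius, the large calf muscle, was taken from C57BL/6 mice aged 3, 12, 24 or 30 months. RNA was sequenced in 2 libraries per age, 8 libraries in all, and the deposited values are counts per gene. The design asks how the transcriptome of this muscle differs from young adulthood to old age. Alternative splicing, which the series also concerns, needs values per exon or junction and was not analysed here. Library totals were 42404254 and 56705929 counts at 3 months, 49903357 and 53184366 at 12 months, 50255485 and 59245029 at 24 months, and 47801556 and 47119535 at 30 months. A count of 0 in a library allows a level of up to 0.0506 to 0.0707 CPM (counts scaled to the library total), a limit that covers counting error only. Ttn, which encodes the giant sarcomere protein titin, took 13.9% to 17.8% of the counts of a library. Genes of the mitochondrial genome took 2.54% to 3.89%. Across genes, log2 CPM of libraries of the same age correlated at 0.982 to 0.990. Their counts differed by more than sampling noise, with a chi-square per degree of freedom of 44.1 to 109. The labels do not say that the 2 libraries of an age came from separate animals, so p-values measure only the spread between libraries. At 3 months that spread may be technical, and the later ages are taken up below. Ddx3y, a gene of the Y chromosome, was at 70.1 to 124 CPM, so every library held male RNA.

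The libraries fell into 2 sets, with both libraries of 3 months in 1 of them and each later age in both. Both libraries of 3 months, replicate 1 of 12 months, replicate 1 of 24 months and replicate 2 of 30 months held transcripts of kidney genes such as Lrp2, Umod and Slc34a1. The summed level of 9 such genes was 63.2, 19.6, 6.11, 4.69 and 3.25 CPM in these 5 libraries, in that order, and 0.0975 to 0.176 CPM in the other 3. Of 19 further kidney genes, listed before their levels were looked at, 19 had a higher mean in the 5 libraries and 8 were higher in all 5 than in all 3. Their summed level was 27.2, 15.1, 12.9, 12.5 and 16.8 CPM in the 5 libraries, in the same order. In the other library of 12, 24 and 30 months it was 11.6, 7.95 and 8.81 CPM. The means thus weigh most on replicate 1 of 3 months, and the 2 libraries of 12 months lay close. At most, summed markers of liver reached 1.43 CPM, testis 0.409, pancreas 0.281, skin 2.22, brain 18.0 and heart 24.0 CPM. A score of 8 circadian clock genes, picked after the libraries were seen to part, followed the same sets. The difference between Dbp and 4 genes taken with it and Arntl and 2 taken with it was 4.11 to 4.41 on the log2 scale in the 3 libraries without kidney transcripts and 0.18 to 2.09 in the 5 with them. Replicates 1 and 2 scored 1.17 and 4.37 at 12 months, 2.09 and 4.41 at 24 months, and 4.11 and 1.42 at 30 months. These gaps argue against repeat libraries of 1 RNA at those ages, though the labels do not say whether the animals were separate. Because 12, 24 and 30 months have 1 library in each set and 3 months has none in the set without kidney transcripts, the number of genes called in each comparison below is also given from a fit with the set as a term. List results against 3 months are given from it where it ended the call or moved the median of a called list beyond 1.5 times, and for lists it added at 30 months. That fit was chosen after seeing the data. Within the set with kidney transcripts the summed kidney level fell with age. Both libraries of 3 months also had the lowest clock scores, 0.28 and 0.18, against 1.17 to 2.09 in the rest of that set. A term with 2 levels, or a difference within that set, therefore leaves kidney and clock differences in the comparisons with 3 months.

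**Figure D1:**
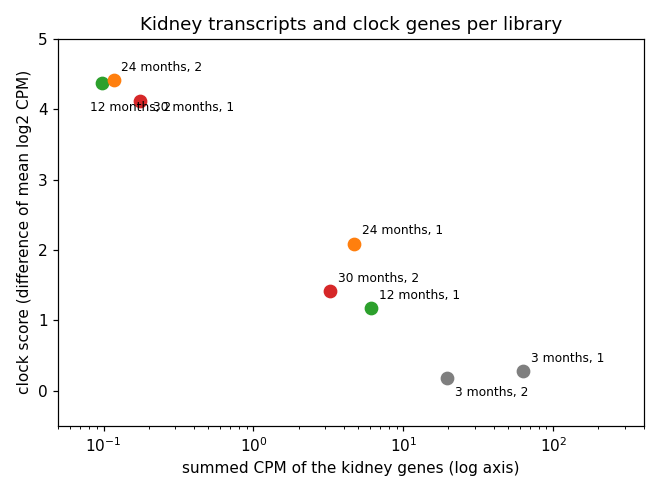
Each point is a library, labelled with its age and replicate. The x axis is the summed CPM of 9 kidney genes (log axis) and the y axis the clock score, the mean log2 CPM of 5 clock genes minus that of 3 others, all picked after the libraries were seen to part. The 3 libraries at 0.0975 to 0.176 CPM have clock scores of 4.11 to 4.41.

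Muscle of 30 months differed from muscle of 3 months in a small group of genes, most of them higher in old muscle. Cpne2, which encodes a calcium-dependent membrane-binding protein (ENSMUSG00000034361, chromosome 8, 94532990 to 94570531, GRCm38), had a mean of 5.82 ± 0.37 CPM at 3 months and 31.9 ± 1.4 CPM at 30 months (SD, n = 2). Its log2 fold change was 2.45 (SE 0.16, adjusted p = 0.000296). Krt18, a keratin listed here among genes of the denervation response, was at 0.114 ± 0.083 and 7.98 ± 2.5 CPM, a log2 fold change of 6.14 (SE 0.50, adjusted p = 0.00146). Myh7, the myosin heavy chain of slow fibres, was at 100.4 ± 33 and 685 ± 290 CPM, a log2 fold change of 2.77 (SE 0.35, adjusted p = 0.028). Eda2r, a receptor of the tumour necrosis factor family and a target of p53, was at 20.3 ± 1.7 and 64.0 ± 14 CPM, with a log2 fold change of 1.65 (SE 0.23, adjusted p = 0.0387).

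The plasma cell immunoglobulin gene Ighg2c was higher by 4.18 on the log2 scale, and Srrm4os by 2.13. Ttc9 was higher by 1.68, the kinase gene Prkcz by 1.62, Tmem132b by 1.55, the NF-kappaB subunit gene Nfkb2 by 1.39 and the stress-responsive kinase gene Plk2 by 1.02. Lower at 30 months were Slc38a4, an amino acid transporter gene, by -1.37 on the log2 scale, and Wdfy1 by -1.23. Adjusted p-values of these 9 genes lay between 0.00293 and 0.0473. Of them, Ighg2c and Tmem132b differed from 3 months about as much by 12 months, though without a call there. Their means were 0.544 and 5.64 CPM at 3 months, 9.47 and 17.0 CPM at 12 months, and 9.88 and 16.5 CPM at 30 months. In the annotation Srrm4os overlaps Srrm4, Nfkb2 overlaps Psd, Wdfy1 overlaps Mrpl44, and Myh7 overlaps noncoding RNA genes such as Mhrt. The strand setting of the counting is not given in the sources used here, so reads of such pairs may be mixed. Also higher was mt-Nd3, a subunit of respiratory complex I encoded in the mitochondrial genome, by 4.90 (SE 0.24). Its transcript matches that of the nuclear copy Gm28438 at 344 of 345 bases, and Gm28438 was lower by -5.39, so the level of either gene is uncertain.

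In all, 29 of 19571 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 24 higher and 5 lower at 30 months. DESeq2 called 207 genes and no low count filter gave 378. The fit with the library set as a term called 416 genes, 290 higher and 126 lower, and kept the 29. That number rests on the 3 month libraries being placed with the set that has kidney transcripts, since placing them on the other side gave 572. Of the 29 genes, 9 passed without replicate 1 of 3 months and 8 without replicate 2, and neither Myh7 nor Eda2r was among them in either fit. The count was 10 and 9 without these libraries, 16 without replicate 1 and 15 without replicate 2 of 24 months, and 51 without replicate 1 of 30 months. With the replicate number as a block it was 13, with a stricter filter 9, and without mitochondrial and repeat genes 6. In the last of these fits most of the lost calls were of genes that stayed in it, not of the genes left out. Leaving out genes with low p-values makes the adjustment stricter for the rest. Calls with an adjusted p near 0.05 thus rest in part on the mitochondrial and repeat genes. The 7 genes that passed in each of the 8 fits that leave out 1 library were Cpne2, Krt18, mt-Nd3, mt-Tg, Gm28438, Gm10800 and Gm15446, of which mt-Tg, Gm28438, Gm10800 and Gm15446 were named after their values were seen. In simulated counts with 200 changed genes, the test recovered 76.7% of 4-fold, 25.7% of 2-fold and 3.6% of 1.5-fold changes between 30 and 3 months, and called 9.2 unchanged genes per run on average. Over 5 runs together the recovered genes numbered 253, 86 and 12. Unchanged genes thus made up a larger share of the simulated calls than the 0.05 aimed at.

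Within the set with kidney transcripts, where 1 library of 30 months can be set against both of 3 months, differences in log2 CPM were 2.40 for Cpne2, 3.18 for Myh7, 1.41 for Eda2r, 1.26 for Nfkb2 and -1.52 for Slc38a4. Genes were named only where the libraries of 30 and 3 months did not overlap, so the sign of these differences was fixed beforehand. The same libraries also entered the calls. The set without kidney transcripts holds no library of 3 months. Kl, called lower at 30 months with a log2 fold change of -2.81, is itself a gene expressed in kidney and was named after its values were seen. It was at 1.60 and 1.00 CPM at 3 months, the libraries with most kidney transcripts, and at 0.156 to 0.331 CPM in the other 6.

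**Figure D2:**
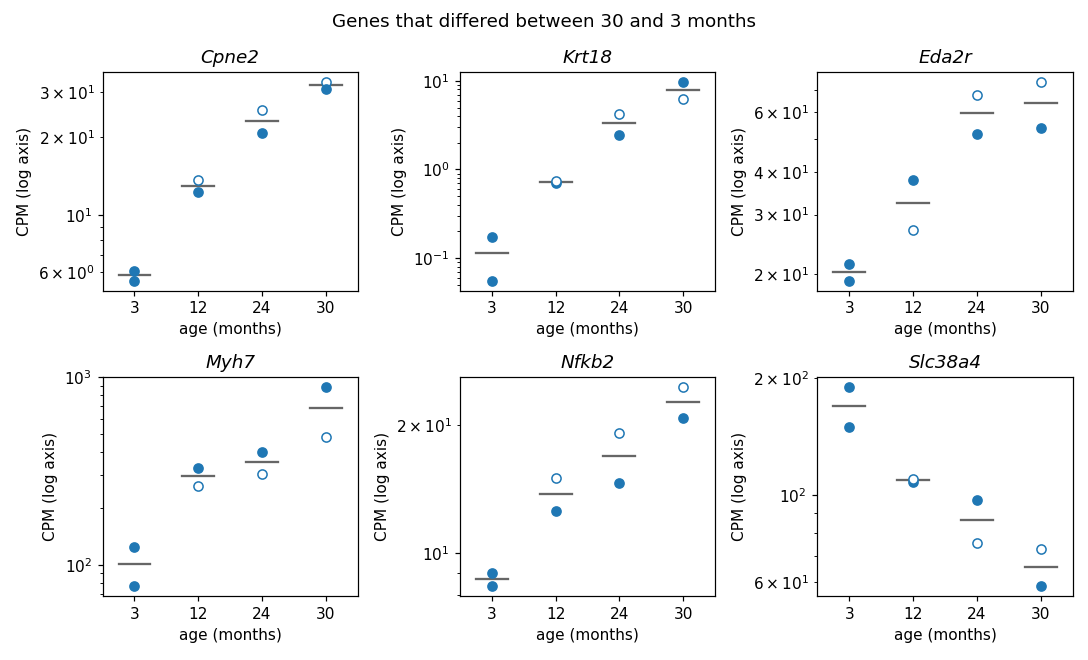
CPM (log axis) of 6 genes in the 8 libraries by age in months. Points are libraries, filled for the 5 with kidney transcripts and open for the 3 without, and bars are the means of 2 libraries. Mean Cpne2 was 5.82, 13.0, 23.2 and 31.9 CPM at 3, 12, 24 and 30 months.

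At 24 months, Cpne2 was already higher than at 3 months, with a log2 fold change of 1.99 (SE 0.16, adjusted p = 0.00139), and so were Ighg2c by 4.33, Srrm4os by 1.90 and Tmem132b by 1.75. Rian, a noncoding RNA of an imprinted cluster, was lower by -1.26 and Wdfy1 by -1.16. The rise of mt-Nd3 was 4.85. Of all genes, 16 were higher and 4 lower, 20 together. Fitted with the library set, the count was 71, DESeq2 gave 131, no filter 233, and only the 4 libraries compared 48. It was 5 without replicate 1 of 3 months, 7 without replicate 2, 6 without replicate 2 of 24 months and 32 without either library of 30 months. With the replicate number as a block it was 9.

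Between 12 and 3 months the difference was mostly a step in a few genes. At 12 months mt-Nd3 was higher by 4.64 (SE 0.24, adjusted p = 0.000074) and Wdfy1 was lower by -1.21 (SE 0.15, adjusted p = 0.0404). Wdfy1 stood at 18.8 ± 0.46 CPM at 3 months and at 8.10 ± 0.53, 8.37 ± 0.70 and 7.98 ± 0.43 CPM at the 3 later ages. Altogether 8 genes passed, 5 higher and 3 lower, and 1 passed once genes of the mitochondrial genome, their nuclear copies and satellite-like genes were left out. Wdfy1 is unlikely to be that gene. Its unadjusted p in the quasi-likelihood test was 1.65e-05, against 8.15e-08 for Gm15446, which also stayed in that fit and was named after its value was seen. With the library set as a term 29 passed, DESeq2 called 66 and no filter gave 134. The count was 5 without replicate 1 of 3 months, 4 without replicate 2, 5 without replicate 2 of 12 months and 14 without either library of 30 months.

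**Figure D3:**
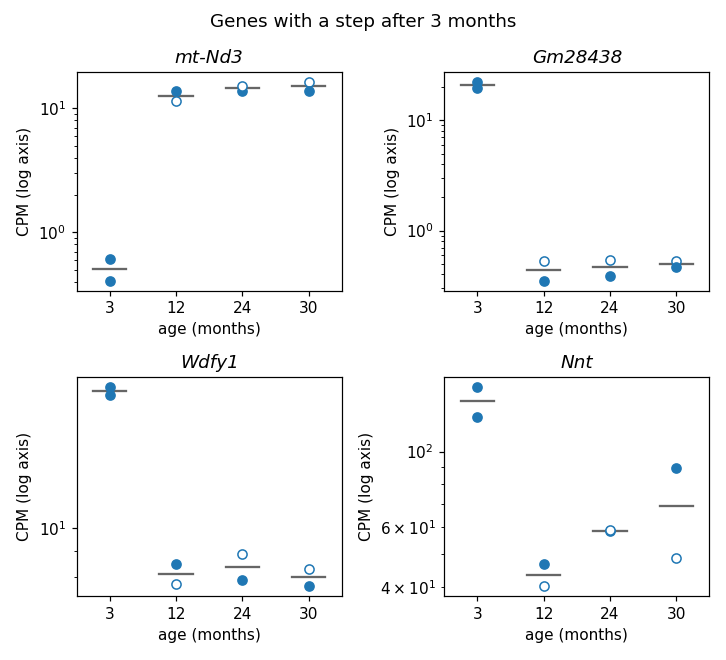
CPM (log axis) of mt-Nd3, Gm28438, Wdfy1 and Nnt by age in months. Points are libraries, filled for the 5 with kidney transcripts and open for the 3 without, and bars are means of 2 libraries. Wdfy1 fell from a mean of 18.8 CPM at 3 months to 8.10 CPM at 12 months.

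Between 24 and 12 months no gene passed, with 600 genes at an unadjusted p under 0.05 against 979 expected by chance. DESeq2 called 2 genes, limma-voom 0 and the fit with the library set 0, and 17 passed with no low count filter. Without replicate 1 of 24 months 6 genes passed. Between 30 and 24 months no gene passed either, with 606 at an unadjusted p under 0.05. DESeq2, limma-voom and the fit with the library set called 0, no filter gave 13, 7 passed without replicate 1 of 24 months and 1 without replicate 1 of 30 months. Between 30 and 12 months Gm10800, a gene in satellite-like sequence named after its value was seen, was the single call, with a log2 fold change of 2.22 and an adjusted p of 0.0401. No low count filter gave 139 genes here, and DESeq2 and the fit with the library set gave 55 each. No gene passed without either library of 3, 12 or 24 months or without replicate 2 of 30 months, and 8 passed without replicate 1 of 30 months.

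Of the 55 genes called between 30 and 12 months with the library set as a term, 46 were higher and 9 lower. Among them, and named after their values were seen, Krt18 was higher by 3.47 (SE 0.38), Krt8 by 3.74, the macrophage gene Mpeg1 by 1.61, the chemokine receptor gene Ccr2 by 1.69, and Ptprc, which marks white blood cells, by 1.11. In that fit 3 of 20 macrophage and monocyte genes passed over all genes, Mpeg1 and Ccr2 among them. In the T and NK cell, B and plasma cell, and neutrophil and mast cell lists 0 passed. Of other lists, 3 of 22 denervation response genes and 2 of 22 complement and cytokine genes passed as higher, and 2 of 19 immediate early genes as lower. The interferon response, MHC class I, p53, antioxidant, and ubiquitin and atrophy lists each had 1 gene higher. For this comparison each set holds 1 library of each age, and the differences in the 2 sets, which share no library, correlated across genes at a Pearson r of 0.251 and a Spearman rho of 0.235. The same correlation was 0.047 for 24 against 12 months and 0.081 for 30 against 24 months. Genes are not independent replicates.

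Across the 4 ages 12 genes passed, among them mt-Nd3, Cpne2, Srrm4os and Wdfy1. Adjusted p-values were 0.000252 for mt-Nd3, 0.0017 for Cpne2, 0.00948 for Srrm4os and 0.0272 for Wdfy1. The count was 0 in a test of 12, 24 and 30 months alone, 4 without replicate 1 of 3 months, 7 without replicate 2, 37 without replicate 1 of 30 months and 28 without replicate 2. With the library set as a term it was 203, and DESeq2 called 226.

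A linear change with age was called for 26 genes, 22 rising and 4 falling. Cpne2 rose by 0.087 on the log2 scale per month (SE 0.006, adjusted p = 0.000226), Srrm4os by 0.080, Eda2r by 0.064, Prkcz by 0.059 and Plk2 by 0.038. None passed when the slope was fitted over 12, 24 and 30 months alone. The count was 5 without replicate 1 of 3 months, 9 without replicate 2, 69 without replicate 2 of 12 months, 16 without replicate 1 of 24 months and 48 without replicate 2 of 30 months. The fit with the library set called 295 and DESeq2 287.

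Slow fibre genes were higher as a group at 30 months. All 12 measured members had positive log2 fold changes, with a median of 1.46, and 11 passed when adjusted over the list alone and 1, Myh7, over all genes, or 7 with the library set as a term. The slow troponin T gene Tnnt1 had a log2 fold change of 2.28 (SE 0.36), the slow calcium pump gene Atp2a2 1.47 (SE 0.30) and Myh7b 1.45 (SE 0.30). The list passed camera with the preset correlation (adjusted p = 5.38e-12) and in each fit that leaves out 1 library, and did not pass with an estimated correlation (adjusted p = 0.547). The median was 0.59 at 12 months and 0.88 at 24 months against 3 months, and both calls were lost without replicate 2 of 3 months (adjusted p = 0.0881 and 0.0597) and with an estimated correlation (0.794 and 0.751). The summed level of 6 heart markers was 24.0 CPM in replicate 2 of 30 months and 8.68 to 13.9 CPM in the other 7 libraries. Within the set with kidney transcripts the median of the slow fibre list was 1.74 at 30 months. No member of the fast fibre list passed, and its median was -0.10, or -0.35 with the library set as a term (adjusted p = 0.012, 0.663 with an estimated correlation). Myh1 and Myh2, myosins of fast fibres, had log2 fold changes of 0.53 and 0.60, which turned to -0.20 and -0.20 without replicate 2 of 30 months.

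Genes of the denervation response, which muscle turns on when it loses its nerve supply, had a median log2 fold change of 0.71 between 30 and 3 months, and 20 of 22 were positive. Krt18 passed over all genes, 12 members passed when adjusted over the list alone, and 8 passed over all genes with the library set as a term. Runx1 had a log2 fold change of 1.32 (SE 0.23), the acetylcholine receptor gene Chrna1 1.13 (SE 0.22) and the growth arrest gene Gadd45a 1.34 (SE 0.27). With the preset correlation the adjusted p was 2.02e-08, it was at most 1.28e-05 in the fits without 1 library, and with an estimated correlation it was 0.383. Of 17 measured neuromuscular junction genes 15 were positive, with a median of 0.24 and Chrnd at 1.31 (SE 0.36). Its adjusted p was 0.00498 with the preset correlation, 0.132 without replicate 1 of 3 months and 0.620 with an estimated correlation. Sarcomere structure genes had a median of 0.37, with no member passing over all genes, or 2 with the library set as a term, and Actn2 at 0.88 (SE 0.27). Regeneration genes had a median of 0.44, or 0.24 with the library set as a term, where 3 members passed. They had embryonic Myh3 at 1.88 (SE 0.42), and lost their call without replicate 1 of 3 months or replicate 2 of 30 months (adjusted p up to 0.121). Sarcomere genes lost theirs with the library set as a term (median 0.20, adjusted p = 0.0689). Estimated correlation gave adjusted p-values of 0.620 and 0.579 for these lists. The p53 and senescence list had a median of 0.18, with Eda2r and Plk2 passing, and its adjusted p of 0.00188 was 0.0617 without replicate 1 of 30 months and 0.547 with an estimated correlation.

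Glycolysis genes lay lower at 30 months, with a median of -0.32, 3 of 18 positive and no member passing, or -0.50 and 1 member lower with the library set as a term. The phosphoglycerate kinase gene Pgk1 had a log2 fold change of -0.59 (SE 0.20) and Ldha, lactate dehydrogenase, -0.56 (SE 0.23). The adjusted p was 0.00188 with the preset correlation, up to 0.55 without replicate 2 of 3 months or replicate 2 of 30 months, where the call was lost, and 0.763 with an estimated correlation. Collagen and matrix genes had a median of -0.52, with 6 of 31 positive. Col1a1, the main chain of type I collagen, was at 476 ± 41 CPM at 3 months and 132 ± 8.1 CPM at 30 months, a log2 fold change of -1.85 (SE 0.54, adjusted p = 0.344). The list had an adjusted p of 5.39e-05, at most 0.0499 without 1 library, and 0.763 with an estimated correlation. With the library set as a term its median was -0.19 (adjusted p = 0.0689). Fibroadipogenic progenitor genes, which mark the connective tissue cells of muscle, had a median of -0.33 (adjusted p = 0.0332). That call was lost without replicate 2 of 3 months or replicate 1 of 30 months (adjusted p up to 0.273) and with the library set as a term (median -0.07, adjusted p = 0.509), and the adjusted p was 0.763 with an estimated correlation.

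Of the lists of immune genes, 5 were called higher at 30 months with the preset correlation and 0 with an estimated one, and T and NK cell and neutrophil and mast cell lists were not called. All 15 measured B and plasma cell genes were positive, with a median of 1.08, Ighg2c passing over all genes and 6 passing when adjusted over the list alone. The adjusted p was 1.11e-08 with the preset correlation, at most 9.08e-06 without 1 library, and 0.205 with an estimated correlation. All 16 genes of MHC class I and antigen processing were positive, with a median of 0.43 and Tap1 at 0.62 (SE 0.21). Adjusted p-values were 7.26e-06 and 0.579 with the preset and the estimated correlation. Complement and cytokine genes had a median of 0.43, with the chemokine gene Ccl8 at 2.53 (SE 0.51), an adjusted p of 0.000112 and one of 0.620 with an estimated correlation. None passed over all genes, or 7 with the library set as a term. All 27 interferon response genes were positive, with a median of 0.69, but the list rested on replicate 2 of 30 months. Without that library the direction turned and the adjusted p was 0.726, against 4.13e-05 with it and 0.763 with an estimated correlation. Macrophage and monocyte genes had a median of 0.62 and an adjusted p of 0.000197, which was 0.36 without replicate 2 of 30 months and 0.763 with an estimated correlation. No macrophage gene passed over all genes, and Lyz2 was at 0.81 (SE 0.38). With the library set as a term 11 of the 20 passed, all higher, and the median was 0.92 (adjusted p = 5.23e-13, 0.284 with an estimated correlation).

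At 12 and 24 months, as at 30, B and plasma cell genes lay higher than at 3 months, with medians of 0.59, or 0.94 with the library set as a term, and 1.56 (adjusted p = 0.00014 and 4.08e-07, and 0.446 and 0.294 with an estimated correlation). Collagen and matrix genes lay lower at both ages, with medians of -0.30 and -0.63, or -0.11 and -0.37 with the library set as a term (adjusted p = 0.794 and 0.751 without that term and with an estimated correlation). The call at 12 months was lost in that fit (adjusted p = 0.0854) and without replicate 2 of 12 months, where the direction turned (adjusted p = 0.881). Immediate early genes had a median of 0.46 at 12 months and interferon response genes one of -0.29, and tendon and cartilage genes had a median of -0.86 at 24 months. With an estimated correlation the adjusted p of these 3 lists was 0.794, 0.794 and 0.751. The interferon call at 12 months was lost without replicate 1 of 3 months or replicate 1 of 12 months, and with the library set as a term (median -0.12, adjusted p = 0.125). Also called at 12 months were denervation (0.30), heat shock (0.26) and blood genes (0.67, adjusted p = 0.0385), each lost without 1 or another library, with an adjusted p of 0.794 with an estimated correlation. At 24 months the remaining calls were denervation (0.36), neuromuscular junction (0.26), sarcomere (0.36), p53 (0.14), lipid synthesis (-0.39) and fibroadipogenic progenitor genes (-0.44, adjusted p = 0.00793). Estimated correlation gave these 0.751, or 0.888 for the last, and all but denervation were lost without 1 or another library. With the library set as a term the p53 (0.06) and fibroadipogenic (-0.29) calls were lost, at an adjusted p of 0.074 each, and the neuromuscular junction median was 0.09.

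Between 30 and 12 months 5 lists were called higher at 30 months with the preset correlation in each of the 8 fits without 1 library, which were run for the later pairs after seeing the data. With an estimated correlation their adjusted p was 0.672 or, for macrophages, 0.783. Interferon response genes had a median of 1.09, macrophage and monocyte genes 0.71, MHC class I genes 0.48, slow fibre genes 0.95 and denervation genes 0.63. Within the set with kidney transcripts the medians were 1.58, 0.84, 0.72, 1.10 and 0.83, and in the set without them 0.23, 0.54, 0.24, 0.73 and 0.27. Of all lists, 12 passed between 30 and 12 months, 10 between 30 and 24 months and 5 between 24 and 12 months, and 5, 4 and 1 of these did so in each fit without 1 library. With an estimated correlation 0 passed.

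In all, camera with the preset correlation called 15 of 41 lists between 30 and 3 months, 11 between 24 and 3 months and 9 between 12 and 3 months. The fit with the library set called 19, 16 and 13. With an estimated correlation 0 lists passed in each comparison, and fry called 0 lists as moving in a single direction. The fry test for mixed change, where members may move either way, called 7 lists at 30, 7 at 24 and 2 at 12 months against 3 months. It called 3 between 30 and 12 months and 0 for the other later pairs. Of the 15 lists, 7 passed in each of the 8 fits without 1 library. Of 11 and 9, it was 5 and 3. Nuclear noncoding RNA, used as a sign of RNA quality, was lower at 30 months with a median of -0.32 (adjusted p = 0.0022, 0.547 with an estimated correlation, 0.0742 without replicate 1 of 30 months), though Malat1 was at 0.07 (SE 0.25) and Neat1 at -0.29 (SE 0.27). This list was lower at 12 and 24 months too, with medians of -0.62 and -0.49 (adjusted p = 0.446 and 0.751 with an estimated correlation). The library set as a term moved the medians at 24 and 30 months to -0.32 and -0.21. Lists that camera did not call between 30 and 3 months included endothelial genes (median -0.17), adipocyte genes (-0.07), tendon and cartilage genes (-0.30), satellite cell genes (0.03), Schwann cell and nerve genes (0.34), blood genes (0.39), T and NK cell genes (0.46), neutrophil and mast cell genes (0.55) and pericyte and smooth muscle genes (0.26). Further uncalled lists were nuclear oxidative phosphorylation (-0.07), citric acid cycle (-0.12), fatty acid use (0.07, with a mean of -0.04), lipid synthesis (-0.31), ubiquitin and atrophy (-0.10), proteasome (0.07), autophagy (0.09), growth signalling (0.15), antioxidant (0.05), heat shock (0.20), the clock (0.34), immediate early (0.17), splicing factors (0.05), ribosomal proteins (0.02) and calcium handling (-0.01, with a mean of 0.30). The mitochondrially encoded list had a median of -0.07 with camera's direction up, since mt-Nd3 and mt-Nd4l rose by 4.90 and 4.06. The transcript of mt-Nd4l matches that of the nuclear copy Gm10222 at 294 of 294 bases, and Gm10222 was lower by -4.61, so the level of mt-Nd4l is uncertain too. With the library set as a term camera called 6 of these lists higher: mitochondrially encoded (median 0.24), heat shock (0.26), neutrophil and mast cell (1.05), pericyte and smooth muscle (0.32), Schwann cell and nerve (0.54) and blood (0.78). Their adjusted p-values lay between 0.00155 and 0.0494, and between 0.629 and 0.777 with an estimated correlation.

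**Figure D4:**
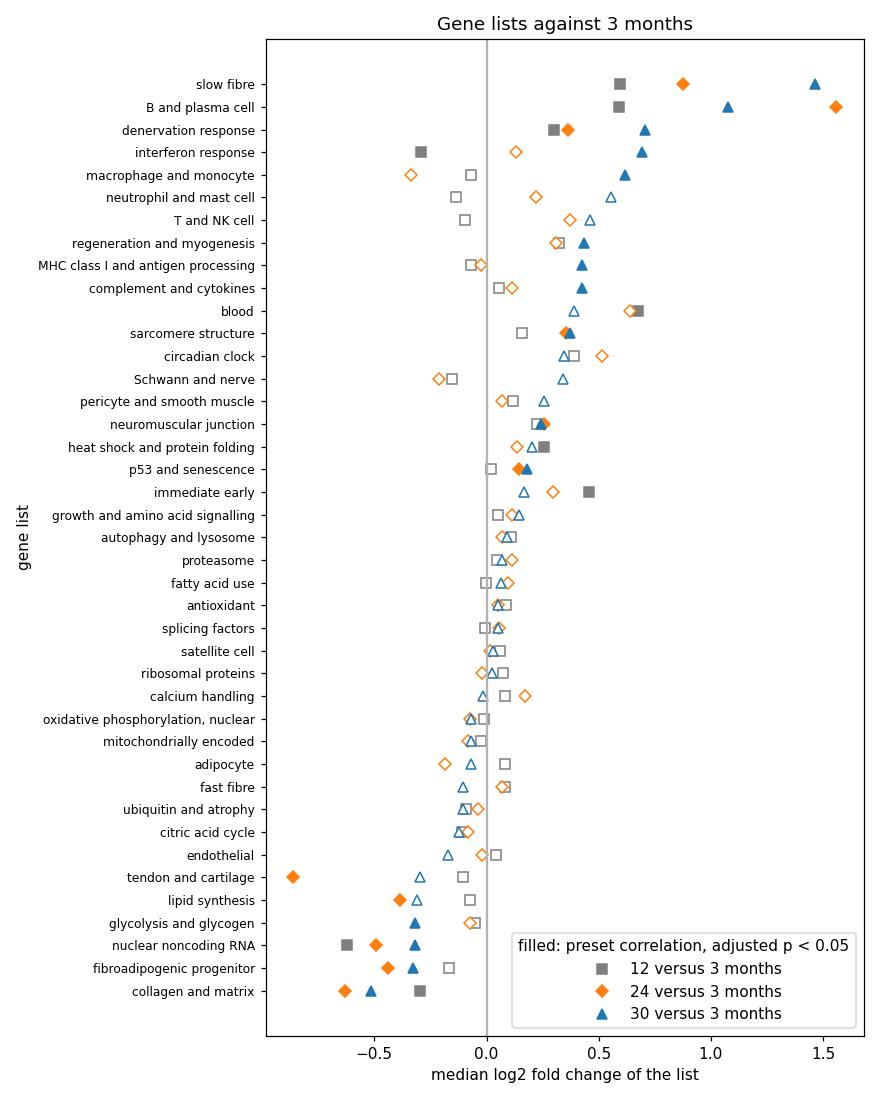
Median log2 fold change of each of 41 gene lists against 3 months (x axis), for 12, 24 and 30 months. Filled symbols passed camera with the preset correlation, and no list passed with an estimated correlation. The slow fibre list has medians of 0.59, 0.88 and 1.46.

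Contrasts that share no library resembled each other weakly. Log2 fold changes of 24 against 3 months and of 30 against 12 months correlated across 19571 genes at a Pearson r of 0.154 and a Spearman rho of 0.085, and 15 of the 20 genes called in either had the same sign. For 24 against 12 and 30 against 3 months the values were 0.203 and 0.135, with 24 of 29 of the same sign. The correlation of the former pair was -0.044 without replicate 1 of 12 months, 0.029 without replicate 1 of 24 months and 0.021 without replicate 1 of 30 months, and that of the latter 0.03 without replicate 1 of 12 months. Contrasts against the shared 3 month libraries correlated at 0.668 to 0.758, against 0.503 to 0.505 in simulated unchanged groups, and the covariance exceeded the simulated one by 0.106 to 0.151. Contrasts of 24 and 30 months against 3 months shared 13 higher and 3 lower calls, against 0.05 and 0 in simulated unchanged groups with the same shared controls. Those groups hold no difference between the library sets, which each contrast with 3 months carries in part. With the fitted set differences put in, a simulation added after the result was seen, the correlations were 0.620 to 0.625, the covariance was exceeded by 0.085 to 0.130, and 0 higher and 0 lower calls were shared.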

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

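The fits with the library set as a term, without the 3 month libraries and without mitochondrial and repeat genes were chosen after the result was seen. Comparisons with 3 months are given in the order 12, 24 and 30 months, then the later pairs 24 against 12, 30 against 12 and 30 against 24, the ages and the slope; reported counts were 8, 20, 29, 0, 1, 0, 12 and 26. The cause was not tested for what follows, except that fewer genes or libraries enter some fits. No low count filter gave 134, 233, 378, 17, 139, 13, 469 and 107 genes. DESeq2 gave 66, 131 and 207, then 2 and 55, 226 and 287. The library set as a term gave 29, 71 and 416, then 55 for 30 against 12 months, 203 and 295. The stricter filter gave 5, 8 and 9, 0 for 30 against 12 months and 16 for the slope. The replicate block gave 5, 9, 13 and 0, where deviations of equal replicate numbers correlated at -0.357 to 0.262 between ages. Without mitochondrial and repeat genes 1, 4 and 6 passed, 0 for 30 against 12 months and 4 across the ages. In the comparisons with 3 months, some genes that stayed in that fit lost their calls too. A minimum change of 1.5 times gave 9 and 13 at 24 and 30 months and 0 for 30 against 12 months. Library totals gave 13 at 24 months and 3 for 30 against 12 months, limma-voom 10 at 24 months, and only the 4 libraries compared 48 at 24 months and 0 for 30 against 12 months. Without the 3 month libraries 0 passed across the ages and for the slope. Lists numbered 9, 11 and 15, and 0, 0 and 0 with an estimated correlation.

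With each library left out, counts were 4 to 14, 5 to 32, 9 to 51, 0 to 6, 0 to 8, 0 to 7, 4 to 37 and 5 to 69, and lists 6 to 14, 10 to 15 and 16 to 18. The agreement of 24 against 3 with 30 against 12 months, 0.154, was -0.044 to 0.264, and that of 24 against 12 with 30 against 3 months, 0.203, was 0.03 to 0.26. RLE size factors and a prior count of 0.5 moved no count of lists or genes beyond 1.5 times.

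Of 167 values of named genes 29 passed, and 5 of these passed in each alternative. Over 3149 alternatives to these values 2852 kept direction and side, 183 lost the threshold, 91 gained it and 23 reversed, all but 3 of the last with a library left out. With each library left out, these log2 fold changes between 30 and 3 months changed sign: Plin4 ran from -0.19 to 0.043, Fabp4 from -0.26 to 0.11, Gabarapl1 from -0.081 to 0.55, Myh2 from -0.20 to 1.11, Myh1 from -0.20 to 1.02, Lpl from -0.039 to 0.72, Smoc2 from -0.20 to 0.14, Scd1 from -1.42 to 0.011. So did those of Mrc1, from -0.15 to 0.29, Mcpt4, from -0.19 to 0.70, Malat1, from -0.11 to 0.23, Abcc9, from -0.22 to 0.13, Mbp, from -0.12 to 0.88, Pmp22, from -0.68 to 0.34, Cd2, from -0.066 to 0.62. Smoc2 was at 0.00078 with library totals and 0.0084 with the library set as a term, and Pmp22 at 0.18 with the latter. Floors of 0.0506 to 0.0707 CPM limit what a count of 0 shows.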

Other observations

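A few further genes were called for a linear change with age and were picked after their values were seen. Ryr2, the calcium release channel of heart muscle, was at 0.324 and 0.278 CPM at 3 months and 1.93 and 3.16 CPM at 30 months, with a slope adjusted p of 0.00168. Trp63, a relative of p53, and Ampd3, an AMP deaminase, rose with slope adjusted p-values of 0.0161 and 0.0299. Sln, a small regulator of the calcium pump and a member of the calcium handling list, did not pass: it was at 51.1 CPM in replicate 2 of 30 months and 12.2 CPM in replicate 1, against 1.17 and 1.33 CPM at 3 months, with an adjusted p of 0.14.

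The tests here of the clock, of kidney RNA, of mitochondrial transcription as a whole and of differing DNA copies were chosen after the result was seen, and so were the fits with the library set. The first pattern is a step between 3 months and the later ages in mt-Nd3 and its nuclear copy Gm28438, with Nnt and Wdfy1. Further genes called in a comparison with 3 months had a like step, among them Tmem132b, Ighg2c, Gm15446 and Rian, picked here after their values were seen. Mean Tmem132b was 5.64 CPM at 3 months and 17.0, 18.9 and 16.5 CPM at 12, 24 and 30 months. A change of mitochondrial transcription as a whole is argued against by the other 10 mitochondrial protein genes, whose median log2 fold change between 30 and 3 months was -0.15 (SD 0.33). The transcripts of mt-Nd3 and Gm28438 are identical at 99.71% of aligned bases and the genes moved in opposite directions, so a sequence variant in the mitochondrial genome that moves reads between copies is a candidate explanation. Whether the 3 month mice were of another C57BL/6 substrain cannot be told apart from age. Of Nnt, Ide and Entpd4, 1 met the bound set beforehand. Nnt was at 155 and 126 CPM at 3 months and 40.2 to 89.3 CPM later. Ide was at 113 and 113 CPM at 3 months and 177 to 321 CPM later, except for 111 CPM in replicate 2 of 30 months. Entpd4, near the floor, was at 0.13 and 0.241 CPM at 3 months and 0.175 to 0.571 CPM later, so its overlap between ages says little. Wdfy1 is also known to differ between C57BL/6 substrains, but was kept out of that test because its step was seen first. A substrain difference would enter each comparison with 3 months. Age itself stays open, as the design names it.

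A second pattern is the rise with age of genes in satellite-like sequence, led by Gm10800 at 0.497 and 0.334 CPM at 3 months and 16.2 and 16.3 CPM at 30 months. For genomic DNA in the older libraries, the summed CPM of olfactory and vomeronasal receptor genes at 30 months was 1.06 times that at 3 months. That ratio cannot decide the question. Receptor genes have few copies and summed to 15.5 to 20.3 CPM in every library. DNA that raised a repeat of many copies could add little to them. DNA copies that set the 3 month mice apart are argued against as the whole source by the median log2 fold change of 2.22 between 30 and 12 months, between 2 and 2.48 without 1 library. From 3 to 12 months the members rose by 2.34 to 4.07 on the log2 scale, most from levels near the floor. Such copies could have added to that step, which the later rise does not test. Of the 31-base words of Gm10801, Gm26870, Gm21738 and Gm10722, 88.3% lay within 2 mismatches in another member, so these genes may be reads of a single repeat family counted under several names. A rise of that family with age remains a hypothesis.

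The third pattern is the main axis of the data, which held 31.2% of the variance and parted the 3 libraries without kidney transcripts from the other 5. RNA from kidney as the whole source is argued against, since 45.9% of the 1123 genes past the threshold for the set were higher in the 3 libraries without it. Total counts correlated with this axis at a Pearson r of 0.578 (exact permutation p = 0.137) and a Spearman rho of 0.571 (exact permutation p = 0.151), and at a Pearson r of -0.141 without the 2 libraries farthest from the median count. The share of the 10 highest genes correlated at 0.648 (exact permutation p = 0.0797) and 0.452 (exact permutation p = 0.267), and at a Pearson r of 0.235 without the 2 libraries farthest from the median share (adjusted over 3 relations, Pearson p = 0.137 and 0.12 for the 2 measures). Leaving out the ends of a range can lower a correlation by itself, so neither measure is settled. The clock score gave 0.969, but over libraries in 2 clusters and with genes picked after the axis was seen, so the relation cannot be tested, and the hour of collection may lie behind the sets but cannot be told apart from another batch that parts them.

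The 416 genes called between 30 and 3 months with the set as a term were set against other choices of 1 library each of 12, 24 and 30 months. The bound fixed before this test, that no other choice gives as many, was not met: the choice of the other library at each age gave 572. That choice is the same model for the later ages with the 3 month libraries moved to the other side, which was recognised only after the test was run, so it says nothing on whether an arbitrary split gives as many. The remaining 6 choices gave 13 to 22 genes.

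Among 50 of the 105 ways to group the 8 libraries into 4 pairs, 4 gave at least the 12 genes found across the ages, the real one included, and the highest other gave 45. Chance is not excluded for that count. The other 3, with 45, 38 and 23 genes, kept the 3 month libraries together, and each paired libraries of different later ages from the same set. A grouping with 7 genes had the same traits. With the set as a term, 203 genes passed across the ages.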
